A study of Mus musculus with 130 samples.

How the data were processed

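The deposited values of 130 Affymetrix Mouse Genome 430 2.0 arrays (45101 probe sets) were used, from muscle, lymph node and blood of BALB/c mice in studies 078-11-008 (115 arrays) and 078-10-007 (15 arrays). Per the labels, the authors made them with Expression Console and the RMA method, and the deposited unit is log2 signal. The version of that program and which arrays were normalized together are not stated. Values ran from -0.72 to 13.13, and array medians were 1.37 in muscle of the larger study, 0.77 in the smaller, 1.41 in lymph node and 1.56 in blood. Values above log2 5 made up 15.2% in muscle of the larger study, 12.8% in the smaller, 16.0% in lymph node and 12.1% in blood. No raw intensities were processed.

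Probe sets were matched to genes with the platform annotation in the reference files. Of all probe sets 34958 carried a single gene, 932 several, 9211 none and 64 were control probes, and the single-gene ones covered 18194 genes. A gene was read from its brightest probe set in each tissue. Sample titles ending in -1 and -2 were averaged as repeat arrays of a replicate, since their values differed with an SD of 0.10 to 0.22, against 0.24 to 0.91 between replicates. Genes with log2 5 or more in at least 3 averaged samples of a fit were tested: 5857 in muscle of the larger study, 4327 in the smaller, 5966 in both together, 5747 in lymph node and 4054 in blood. Genome positions are from GRCm38.p6.

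Group means were fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method within each of 36 contrasts. A gene was called with an adjusted p below 0.05 and a log2 difference of at least 1 (2-fold). Variation of saline between times used the F test of the same fit. Each GLA-SE, GLA and Alum group of muscle was compared with saline of its time, GLA-SE with GLA and with Alum, SE with the Day 1 saline of its study, lymph node with Day 1 saline, and blood with 1 pooled 6 hr saline sample, whose spread was assumed equal to that of the other blood groups. Contrasts across the studies were differences of effects, each against saline of its own study. The largest changes and some list medians are also given relative to the median of all genes where that median exceeded 0.1 in size. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

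Gene lists (31, with 443 of 487 genes on the array) were written by hand before the data were examined and tested with camera from limma, with the preset correlation of 0.01 and with an estimated one, adjusted over the lists of a tissue and study. They covered interferon-stimulated genes, interferon-gamma-inducible GTPases, chemokines, cytokines, the TLR4 pathway, inflammasome, acute phase, complement, MHC class I and II, muscle contraction, regeneration, oxidative metabolism, cell cycle, matrix, endothelial markers and activation, and markers of neutrophils, macrophages, dendritic, T, B, plasma and NK cells, red cells, platelets and adipocytes. A list needed 3 tested members, and eosinophil, mast cell, Schwann cell and keratinocyte lists never had them. Of 696 list results 371 were called with the preset correlation and 14 with the estimated one.

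For each contrast, the 8 largest rises and 6 largest falls were named among called genes whose samples did not overlap (predicted genes without names left out). At SE Day 4, 833 of 1395 called genes had no overlap. In differences of effects and for saline between times overlap was not examined. Up to 4 of the most changed members of each list described were named too. So were 23 genes fixed before the data were examined, among them Tlr4, Cd14, Il6, Cxcl10, Saa3, Ifng, Myog and Acta1. Not all named genes are printed. Those left out, many with a call lost in some setting, were chosen after their values were seen. So were members that moved against their list.

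The alternatives were a random block for repeat arrays (duplicateCorrelation), the replicate number as a block, no filter on dim genes, quantile normalization repeated, the mean of all probe sets of a gene, only the groups compared in the fit, saline of all times pooled, both studies in a joint fit, eBayes with trend and robust, each replicate left out, and camera with an estimated correlation. The groupings, contrasts, thresholds, splits and these alternatives were chosen before the data were examined. Centring of each array and a fit without 2 SE Day 4 libraries were added after. Every division of the samples of a contrast into groups of the same sizes was fitted, or 100 drawn at random. Of genes moved by 1.5 or 3 in log2 in simulated data, limma called 93% and 98.4% in muscle of the larger study. It called 76.2% and 92% in the smaller, 88.8% and 97.8% in lymph node and 90% and 99.8% in blood. Blood values rest on the spread assumed for the pool. For GLA-SE minus SE it called 75.2% and 93.4%. Unchanged genes called numbered 5 to 43. Samples were treated as unpaired.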

Results

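Transcripts were measured on 130 arrays in muscle, lymph node and blood of BALB/c mice given an adjuvant or phosphate-buffered saline (PBS). The adjuvants were GLA (glucopyranosyl lipid A, a synthetic agonist of Toll-like receptor 4), SE (a stable oil-in-water emulsion), GLA in that emulsion (GLA-SE) and Alum. Study 078-11-008 held 90 muscle arrays for GLA-SE, GLA, Alum and PBS at 6 hr and Days 1, 2 and 4, 15 lymph node arrays and 10 blood arrays. Study 078-10-007 held 15 muscle arrays for SE at the same 4 times and PBS at Day 1. Each group had 3 replicates (n = 3), except the saline blood group (1 pooled sample). Muscle of 078-11-008 had 6 arrays per group (in pairs) but 3 in PBS of 6 hr and Day 1. Contrasts with these groups cannot separate that from treatment or time. Values are log2 signals, and differences are given in log2 with ± the standard error from limma. A gene rose or fell where its adjusted p was below 0.05 and its difference was at least 1. Each gene named as a largest change between 2 groups had 3 of 3 treated replicates beyond every control. Overlap was not examined for differences of effects and saline between times. Where the count adjusted over a list alone differed from that over all genes, it follows with the word alone. List counts cover tested members only. A gene dim in saline passed the filter only where other samples were bright, which favours rises. Many saline values lay below log2 2, near the array background, so large folds depend on that background. Acta1 and other bright muscle genes lay near the top of the scale (Acta1 12.76 in saline at 6 hr, highest value of those arrays 12.88), where a small difference does not show that a gene was unmoved. The labels do not say that replicates were separate animals, so every p-value measures spread between samples, and the number of arrays limits precision.

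In muscle at 6 hr, GLA-SE raised Saa3, which codes for an acute phase serum amyloid A, from log2 2.28 (SD 0.86) in saline to 10.57 (SD 0.06), a difference of 8.29 ± 0.64, or 312-fold (n = 3 each, adjusted p = 2.77e-12 by limma). Its probe set was 1450826_a_at, for a gene on chromosome 7 at 46711998 to 46719615 in GRCm38.p6. Cxcl10 (7.35 ± 0.48, 163-fold, probe set 1418930_at, chromosome 5 at 92346638 to 92348889) and Cxcl9 (6.73 ± 0.63), which attract T cells, rose with Cxcl2 (6.61), Cxcl1 (6.32) and Cxcl5 (6.28), which attract neutrophils. The cytokine gene Il6 rose by 7.27 ± 0.36 (154-fold, probe set 1450297_at, chromosome 5 at 30013114 to 30019975), and the myeloid gene Slfn4 rose by 7.25 ± 0.84. Among the largest falls were Cavin2, a caveolar coat gene (-2.39 ± 0.37), the phosphatase gene Dusp10 (-2.16 ± 0.22), the endothelial receptor gene Tek (-2.07 ± 0.16) and the insulin signalling gene Irs1 (-2.03 ± 0.24). Of 5857 genes tested 447 rose and 50 fell.

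At 6 hr all 20 interferon-stimulated genes tested rose (median 3.74), with Ifit1 (5.92), Rsad2 (5.76) and Cmpk2 (4.88), as did all 13 interferon-gamma-inducible GTPases and their partners (median 3.60, Iigp1 5.02) and 9 of 10 MHC class I genes (median 2.08). Adjusted p = 0.0708, 0.129 and 0.162 with an estimated correlation for these lists, all called with the preset correlation. Chemokine genes rose in 13 of 20 (14 alone; median 3.59), with Ccl2 (5.78) and Ccl3 (5.11), and endothelial activation genes rose in 4 of 5, with Icam1 (5.01), Selp (3.85) and Vcam1 (3.36), which hold leukocytes to the vessel wall (adjusted p = 0.0708 and 0.0863 with an estimated correlation). Inflammatory cytokines rose in 6 of 7 (Il1rn 5.29, Il1b 4.67, Csf3 4.58) and TLR4 and NF-kB pathway genes in 13 of 15 (Nfkbiz 5.04, Cd14 4.64, Tnfaip3 3.74). Acute phase and stress protein genes rose in 12 of 15 (14 alone) and neutrophil markers in 5 of 6 (S100a8 5.46, S100a9 4.79). These 4 lists were called both ways, each with adjusted p = 0.048 with an estimated correlation. Macrophage markers rose in 5 of 12 and muscle regeneration genes in 3 of 5 (Gadd45a 2.31, Myf6 1.68, Cdkn1a 1.31), with adjusted p = 0.651 and 0.246 with an estimated correlation. Complement rose in 2 of 10 (Cfb 3.32, C1ra 1.40) and inflammasome genes in 3 of 4, while Kdr (-1.21) and Tek fell among 7 endothelial markers. No contractile or cell cycle gene passed the test, and 1 adipocyte marker rose (Lep 2.63). Actb probes at the 3' end exceeded those at the 5' end by 1.30 (SD 0.10) with GLA-SE at 6 hr and by 0.64 (SD 0.17) in saline, and Gapdh probes by 0.35 and 0.13, both without overlap. At Day 1 the values were 1.09 and 0.76 for Actb, without overlap, and 0.27 and 0.14 for Gapdh, and at Day 4 1.05 and 1.09 for Actb and 0.41 and 0.57 for Gapdh.

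**Figure D1:**
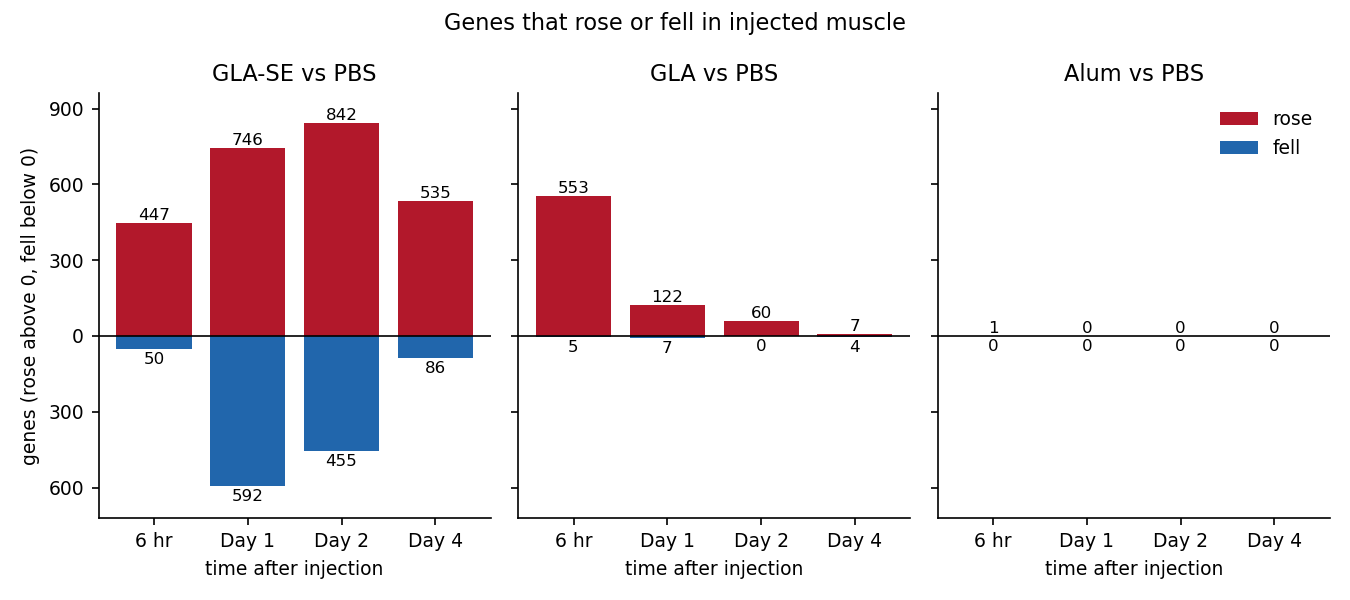
Bars give the number of genes that rose (upward) and fell (downward) in muscle against PBS of the same time for GLA-SE, GLA and Alum at 6 hr and Days 1, 2 and 4, n = 3 per group. GLA-SE moved 497, 1338, 1297 and 621 genes, GLA 558, 129, 60 and 11, and Alum 1, 0, 0 and 0.

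At Day 1 in muscle Saa3 had the largest rise with GLA-SE (8.79 ± 0.64, 444-fold, adjusted p = 2.13e-13, n = 3). Cxcl9 (8.14 ± 0.63), the antimicrobial lipocalin gene Lcn2 (7.64 ± 0.95), the GTPase gene Igtp (7.18) and Cd274, which codes for the inhibitory ligand PD-L1 (6.76 ± 0.53), were also among the largest rises. Ankrd1, a stress-responsive muscle gene (probe set 1420992_at, chromosome 19 at 36111965 to 36119844), rose from 3.46 (SD 2.16) to 11.01 (SD 0.58), by 7.55 ± 1.30 (187-fold, adjusted p = 6.69e-06). Ky, which is needed for neuromuscular function (probe set 1440435_at, chromosome 9 at 102505755 to 102546247), fell from 7.45 (SD 0.09) to 1.76 (SD 0.64), by -5.69 ± 0.29 or 51.7-fold (adjusted p = 9.4e-17). The muscle kinase gene Mylk4 (-4.83 ± 0.30), the methyltransferase gene Mettl11b (-4.68) and the water channel gene Aqp4 (-4.55 ± 0.44) followed. Of all genes tested 746 rose and 592 fell. The median of all genes was -0.11, and relative to it Saa3 rose by 8.90, Ankrd1 by 7.65 and Cxcl9 by 8.25, while Ky fell by 5.58 and Mylk4 by 4.72.

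Every interferon-stimulated gene (20 of 20, median 4.00, 4.11 relative to all genes), interferon-gamma-inducible gene (13 of 13, median 5.42) and MHC class I gene (10 of 10, Tap1 4.55, Psmb9 4.23) rose at Day 1, with adjusted p = 0.246, 0.209 and 0.225 with an estimated correlation. Chemokines rose in 17 of 20 (median 4.11, Ccl2 5.18), acute phase genes in 14 of 15, neutrophil markers in 5 of 6 (median 5.33, S100a8 6.12) and cytokines in 7 of 7 (Il6 6.11, Csf3 2.19). TLR4 and NF-kB pathway genes rose in 13 of 15 while Tirap fell (-1.05). Of the macrophage markers 10 of 12 rose (median 2.45) and of the complement genes 7 of 10 (Cfb 4.28). Muscle regeneration genes rose in 3 of 5 (Gadd45a 2.99, Cdkn1a 2.89, Myf6 2.35). Falls were few among 24 contractile genes (Casq1 -1.42, Ldb3 -1.03; median -0.31) and 18 oxidative genes (Ppargc1a -3.34, Idh3a -1.29; median -0.63). All 15 lists called with the preset correlation were lost, with adjusted p = 0.182 to 0.551 with an estimated correlation.

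At Day 2 Saa3 differed by 9.47 ± 0.64 or 710-fold in muscle (11.34, SD 0.13, against 1.87, SD 0.54, n = 3 each, adjusted p = 9.94e-14). Among the other large rises were the myeloid genes Slfn4 (7.48), Lcn2 (6.86), Ms4a6d (6.84), the formyl peptide receptor gene Fpr2 (6.73), Aif1 (6.18) and S100a8 (6.12), with Cxcl9 (6.15). Il6 was up by 2.64, and Csf3 (0.16) was not called. Among the largest falls were those of the slow fibre light chain genes Myl2 (-7.12 ± 1.89, adjusted p = 0.00145) and Myl3 (-6.45 ± 1.60) and the heavy chain gene Myh7 (-6.14 ± 2.05, adjusted p = 0.00971). Their treated replicates were uneven (Myl2 SD 2.20), and the call of Myh7 was lost without replicate 1 (-6.11) or 2 (-5.41), of Tnnt1 (-5.47) without 1 (-5.46) or 2 (-4.65) and of Tnni1 (-5.29) without 1 (-5.76) or 2 (-4.63). Aqp4 also fell (-5.25 ± 0.44). Myog, a regulator of muscle differentiation, rose by 1.57 ± 0.45 (adjusted p = 0.00259), but not as a call without replicate 2 (1.18). In total 842 genes rose and 455 fell (741 and 597 with quantile normalization, 745 and 581 with centring).

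Oxidative metabolism fell at Day 2 in 15 of 18 genes (median -1.19), with Idh2 (-2.13), Cox7a1 (-1.91), Ndufs1 (-1.55) and Acadm (-1.45), and 6 of 24 contractile genes fell (median -0.45), with Myh2 (-3.89), Mb (-2.82) and Myh1 (-1.38). Adjusted p was 8e-11 for oxidative metabolism with the preset correlation and adjusted p = 0.157 and 0.254 with an estimated correlation for the 2 lists. In these libraries Actb probes at the 3' end exceeded those at the 5' end by 1.43 (SD 0.15), against 0.69 (SD 0.13) in saline, and Gapdh probes by 0.62 against 0.15, both without overlap. With GLA at 6 hr the values were 1.43 against 0.64 and 0.34 against 0.13, and no oxidative gene fell (median -0.13). All 12 macrophage markers rose (median 4.60; Chil3 5.55, Fcgr1 5.32, Cd68 5.21, Lyz2 4.73), as did 5 of 6 neutrophil markers (median 6.05) and 18 of 20 chemokines (median 3.70), with adjusted p = 0.268, 0.197 and 0.242 with an estimated correlation. Interferon-stimulated genes (20 of 20, median 3.89), interferon-gamma-inducible genes (13 of 13, median 3.75) and MHC class I genes (10 of 10, median 3.19) were raised. Complement rose in 8 of 10 (9 alone; C3ar1 5.44) and acute phase genes in 13 of 15. Cell cycle genes rose in 3 of 4 (Mcm5 3.82), MHC class II in 3 of 5 (H2-Ab1 1.51) and extracellular matrix genes in 6 of 18 (5 alone; Mmp3 4.31). All 15 lists called with the preset correlation were lost, with adjusted p = 0.157 to 0.506 with an estimated correlation.

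**Figure D2:**
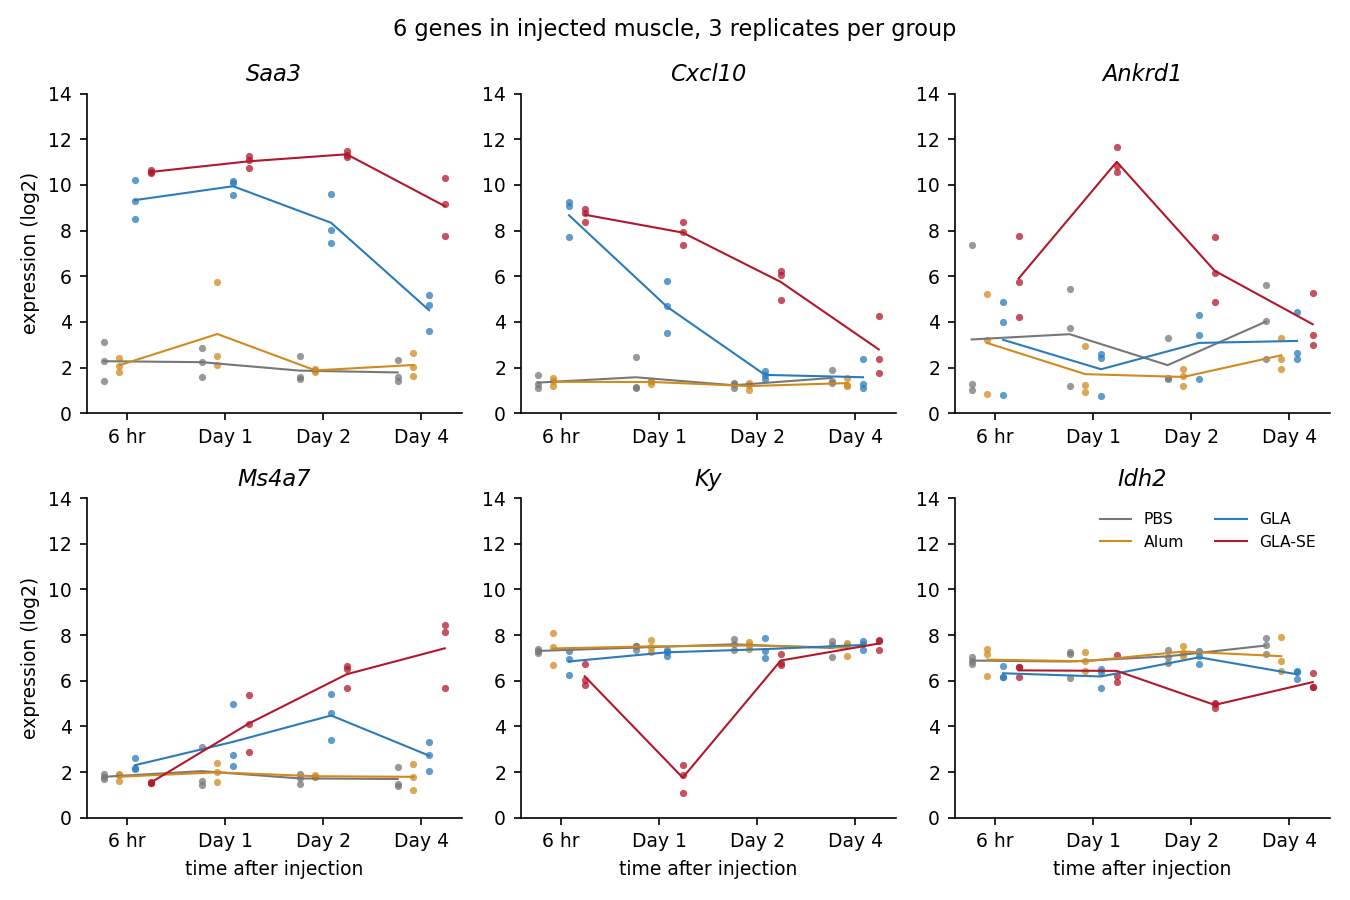
Points are the log2 signals of single replicates in muscle at 6 hr and Days 1, 2 and 4 for Saa3, Cxcl10, Ankrd1, Ms4a7, Ky and Idh2, and lines join the means of PBS, Alum, GLA and GLA-SE (n = 3). With GLA-SE the group means of Saa3 lay between 9.07 and 11.34, and those of Ankrd1 and Ky on Day 1 were 11.01 and 1.76 and that of Ms4a7 on Day 4 was 7.42.

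At Day 4 macrophage genes were among the largest rises in muscle given GLA-SE. Saa3 was up by 7.28 ± 0.64 (156-fold, adjusted p = 7.99e-10), followed by the lysosomal protease gene Ctss (6.04 ± 0.75), the macrophage membrane genes Ms4a7 (5.72 ± 0.61, 7.42 with SD 1.52 in treated muscle, adjusted p = 2.05e-08, probe set 1424754_at, chromosome 19 at 11321039 to 11336146) and Ms4a6d (5.71), the lectin gene Clec4a3 (5.60) and lysozyme Lyz2 (5.49). The slow fibre genes Myh7 (-5.72 ± 2.05, adjusted p = 0.0233) and Myl3 (-5.12) fell, but Myh7 lost its call without replicate 1 (-6.92), 2 (-5.23) or 3 (-5.0) and Myl3 without replicate 1 (-5.98) or 3 (-3.83). Inmt fell in every setting (-2.10 ± 0.43). Il6 (0.24), Cxcl1 (0.12) and Csf3 (-0.16) were not called, while Ccl2 (2.36) and Cxcl10 (1.25, adjusted p = 0.0329) were, but Ccl2 not without replicate 1 (2.00) and Cxcl10 not without replicate 1 (1.64) or 3 (0.41) or with only the groups compared in the fit. Among all genes 535 rose and 86 fell, with 312 called where only the groups compared entered the fit and 982 with no filter on dim genes.

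All 12 macrophage markers rose at Day 4 (median 3.97; Cd68 4.97, Adgre1 4.73), as did 9 of 10 complement genes (10 alone; median 3.69; C3ar1 5.28, C1qb 4.76) and 5 of 5 MHC class II genes (median 2.71; H2-Aa 2.96, H2-Eb1 2.71), with adjusted p = 0.182, 0.246 and 0.254 with an estimated correlation. Interferon-stimulated genes (20 of 20, median 2.48), interferon-gamma-inducible genes (11 of 13, median 2.01) and MHC class I genes (10 of 10, median 2.04) were raised, with adjusted p = 0.246, 0.31 and 0.225 with an estimated correlation. Chemokines rose in 12 of 20 (median 1.71), with Ccl6 (5.37), Ccl9 (4.78) and Ccl8 (4.26), and neutrophil markers in 5 of 6 (median 3.00). Acute phase genes rose in 8 of 15, cytokines in 4 of 7 and extracellular matrix genes in 6 of 18 (Timp1 2.33, Col3a1 2.08). Of the oxidative genes only Idh2 (-1.60) fell. All 15 lists called with the preset correlation were lost, with adjusted p = 0.182 to 0.506 with an estimated correlation. Of 10 ways to divide the samples of each contrast into groups of 3, the real division gave 497, 1338, 1297 and 621 genes from 6 hr to Day 4 and the highest other division 1, 54, 0 and 394. With all probe sets of a gene averaged, the 4 counts were 319, 809, 834 and 395.

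GLA without the emulsion gave a rise of similar size in muscle at 6 hr. Cxcl10 rose by 7.32 ± 0.48 (160-fold, adjusted p = 1.92e-13, n = 3), Saa3 by 7.05 ± 0.64 (133-fold), Slfn4 by 6.80, the antiviral genes Ifit1 by 6.42 and Rsad2 by 6.23, Cxcl9 by 6.42 and Il6 by 5.87 ± 0.36 (58.6-fold). In all 553 genes rose and 5 fell. All 20 interferon-stimulated genes (median 3.94) and all 13 interferon-gamma-inducible genes rose, with adjusted p = 0.0708 and 0.149 with an estimated correlation. Chemokines rose in 16 of 20 (17 alone; median 4.24), cytokines in 7 of 7 (Il1rn 5.14, Csf1 2.62) and TLR4 pathway genes in 11 of 15 (Nfkbiz 4.19), lists that were called both ways (adjusted p = 0.0483, 0.048 and 0.048 with an estimated correlation). Acute phase genes rose in 12 of 15 (13 alone), macrophage markers in 9 of 12 (Fcgr1 3.46), complement in 6 of 10 (7 alone; Cfb 3.41) and MHC class II in 4 of 5 (5 alone). Adipocyte markers rose in 6 of 9 (8 alone; median 2.98; Lep 3.24, Retn 3.04), with library means of 6.53, 8.97 and 9.14 against 5.87 to 6.17 in saline. Of 15 lists called with the preset correlation 12 were lost, with adjusted p = 0.0628 to 0.446 with an estimated correlation. Without replicate 3, 306 genes were called, and 370 with all probe sets of a gene averaged.

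Fewer genes were called for GLA at the later times. At Day 1 Saa3 (7.70 ± 0.64, 208-fold, adjusted p = 3.96e-10), Saa1 (3.89 ± 0.35, adjusted p = 1.44e-09) and Cxcl9 (4.98 ± 0.63, adjusted p = 5.26e-06) were raised, and 122 genes rose and 7 fell. Lcn2 (4.66; 4.37 and 4.07), Cxcl10 and Ifit1 lost their calls without replicate 1 or 2, Cxcl10 at 2.86 and 2.29 and Ifit1 at 3.28 and 2.63. Interferon-stimulated genes rose in 16 of 20 (18 alone; median 2.27; Oasl2 3.07, Irf7 2.91), acute phase genes in 7 of 15 (10 alone) and neutrophil markers in 3 of 6 (5 alone), lists that were called both ways (each adjusted p = 0.048 with an estimated correlation). Interferon-gamma-inducible genes rose in 6 of 13 (12 alone; Gbp3 2.94, Ifi47 2.75), chemokines in 8 of 20 (11 alone; median 1.31) and macrophage markers in 5 of 12 (8 alone). The 9 lists lost of 12 had adjusted p = 0.0708 to 0.335 with an estimated correlation. The count of 129 fell to 16 without replicate 1, 11 without replicate 2 and 17 with only the groups compared in the fit, and was 223 against the 12 saline samples of all times.

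At Day 2 GLA left 60 raised genes and no fallen one, with Saa3 (6.47 ± 0.64, 88.9-fold, adjusted p = 4.33e-08) and the monocyte and macrophage genes Aif1 (3.60), Clec4a3 (3.60), Fpr2 (3.45), Ccr2 (3.27) and Ctss (3.20). Without replicate 1 the calls of Aif1 (3.31), Clec4a3 (3.21), Fpr2 (2.94), Ccr2 (2.88) and Ctss (2.83) were lost, and without replicate 2 those of Clec4a3 (3.07), Fpr2 (3.33), Ccr2 (3.18) and Ctss (2.94). Of the macrophage markers 5 of 12 rose (9 alone; Adgre1 3.19, Lyz2 3.18), of the complement genes 3 of 10 (6 alone; Cfb 3.02, C3ar1 2.93), of the interferon-stimulated genes 2 of 20 (Irf7 2.26) and of the chemokines 0 of 20 (5 alone). All 14 lists called with the preset correlation had adjusted p = 0.0675 to 0.431 with an estimated correlation. Cxcl10 (0.45) and Il6 (-0.08) were not called. Actb ends differed by 1.04 at Day 1 and 0.89 at Day 2 with GLA against 0.76 and 0.69 in saline, without overlap. Counts ran from 1 without replicate 1 and 9 without replicate 2 to 108 without replicate 3, with 8 where only the groups compared entered the fit, 37 with probe sets averaged, 37 with no filter, 128 with a random block and 130 against pooled saline.

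At Day 4 after GLA 7 genes rose, among them the GTPase gene Iigp1 (2.90 ± 0.89, adjusted p = 0.0416), Saa3 (2.73 ± 0.64, adjusted p = 0.0106), the macrophage gene Adgre1 (1.77) and Cd14 (1.60). The 4 falls were in Plin5 (-1.29), Idh2 (-1.26), Chrna1 (-1.17) and Acss1 (-1.06). Relative to the median of all genes (-0.12) Saa3 rose by 2.85, Idh2 fell by 1.14 and Acss1 by 0.94. Quantile normalization gave 9 rises and 1 fall and centring 11 and 1. Saa3 lost its call without each replicate (2.89, 3.08 and 2.21), as did Iigp1 (3.67, 3.81 and 1.23), Adgre1 (2.00, 1.98 and 1.34), Cd14 (2.17, 1.66 and 0.96), Plin5 (-1.38, -1.75 and -0.74), Idh2 (-1.30, -1.50 and -0.98) and Chrna1 (-1.15, -1.36 and -0.99), and Acss1 without replicate 1 (-1.17) or 3 (-0.86). The count was 0, 3 (1 rise and 2 falls) and 1 (a fall) without replicates 1, 2 and 3, 0 with only the groups compared in the fit, 4 against pooled saline, 6 with probe sets averaged, 22 with no filter (4 rises and 18 falls) and 32 with a random block. Interferon-gamma-inducible genes rose in 1 of 13 (6 alone) and macrophage markers in 1 of 12. All 11 lists called with the preset correlation had adjusted p = 0.236 to 0.662 with an estimated correlation. Against 558, 129, 60 and 11 genes from 6 hr to Day 4, the highest other division of the samples gave 5, 0, 0 and 0.

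Alum moved a single gene in muscle. Cebpd, a transcription factor gene of the acute phase (probe set 1423233_at, chromosome 16 at 15887286 to 15889545), rose at 6 hr from 4.76 (SD 0.66) to 6.38 (SD 0.32), by 1.62 ± 0.28 or 3.08-fold (n = 3, adjusted p = 0.0107 by limma). The call was lost without replicate 1 (1.15), 2 (1.87) or 3 (1.86), with probe sets averaged (0.91) and with only the groups compared in the fit, whereas the count was 6 with no filter, 6 with a random block and 26 against pooled saline. Saa3 (-0.18, adjusted p = 0.999), Cxcl10 (0.04) and Il6 (0.02) were not called at 6 hr, and Saa3 (1.23, adjusted p = 0.924) and Cxcl9 (1.16) were not called at Day 1. No gene was called at Days 1, 2 and 4, where limma gave unadjusted p below 0.05 for 277, 99 and 541 of 5857 genes (457 at 6 hr). At Day 4, 10 genes had an adjusted p below 0.05 but differences under the minimum, and there 6 genes were called with no filter and 2 with a random block, which also gave 2 at Day 1. With the preset correlation camera called 6, 8, 3 and 3 lists from 6 hr to Day 4, none kept (adjusted p = 0.246 to 0.593, 0.209 to 0.596, 0.254 to 0.578 and 0.326 to 0.697 with an estimated correlation), and medians were small, such as -0.04 for contractile genes at 6 hr, 0.30 for endothelial markers at Day 1 and -0.20 for oxidative genes at Day 4. For chemokines at 6 hr the median (0.08) and mean (0.02) were positive while camera ranked the list downward. Adipocyte markers had a Day 1 median of 1.55 with none called (adjusted p = 0.266 with an estimated correlation), and library means were 6.41, 6.88 and 8.95 against 5.72 to 6.33 in saline. Each other division of the samples gave 0 genes.

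Against GLA, the emulsion formulation at 6 hr raised the serum amyloid genes Saa1 (2.78 ± 0.35, 6.88-fold, adjusted p = 1.28e-06, n = 3) and Saa2 (2.73 ± 0.26), the granulocyte growth factor gene Csf3 (2.69 ± 0.32), the stress gene Ddit4 (2.45), Thbd (2.41) and Nfil3 (2.24 ± 0.25). Cavin2 (-2.43 ± 0.37) and Tek (-1.81 ± 0.16) were lower. With only the groups compared in the fit Ddit4 and Cavin2 were not called. Il6 was higher by 1.40 (adjusted p = 0.016), a call lost there and without replicate 1 (1.07), 2 (1.85) or 3 (1.27). Cxcl10 (0.03) and Saa3 (1.23, adjusted p = 0.31) were not called. Regeneration genes were higher in 3 of 5 (Gadd45a 1.92, Myf6 1.59, Cdkn1a 1.34; adjusted p = 0.0675 with an estimated correlation) and chemokines in 2 of 20 with 1 lower (2 and 2 alone). No interferon-stimulated gene, MHC class I gene or neutrophil marker was called, and complement was lower in 1 of 10 (4 alone) and MHC class II in 0 of 5 (4 alone). The 9 lists called with the preset correlation had adjusted p = 0.0675 to 0.529 with an estimated correlation. Of 107 genes 64 were higher and 43 lower, 63, 52 and 82 were left without replicates 1, 2 and 3, 42 with only the groups compared in the fit, and 162 with a random block (71 higher and 91 lower). Another division of the samples gave 105 genes.

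At Day 1 GLA-SE exceeded GLA by 9.08 ± 1.30 in Ankrd1 (542-fold, adjusted p = 6.1e-07), 7.38 in the GTPase gene Rrad, 6.95 ± 0.83 in Hspa1a and 6.47 in Hspa1b, heat shock protein 70 genes, 5.60 ± 0.36 in Il6, 5.03 in Ubd and 4.68 in Cd274. Lower were Ky (-5.49 ± 0.29), Mylk4 (-4.63), Mettl11b (-4.18) and Aqp4 (-4.17). Saa3 was not called (1.09, adjusted p = 0.144). Interferon-gamma-inducible genes were higher in 13 of 13 (median 3.29), interferon-stimulated genes in 18 of 20 (median 1.53; Parp14 2.77, Rsad2 2.41) and chemokines in 13 of 20 (median 2.15; Ccl2 3.40), with adjusted p = 0.254, 0.436 and 0.307 with an estimated correlation. Cytokines were higher in 7 of 7 (Il1b 3.48), neutrophil markers in 5 of 6, endothelial activation genes in 5 of 5 and regeneration genes in 3 of 5 (median 2.12; adjusted p = 0.194 with an estimated correlation). Macrophage markers were higher in only 2 of 12, and lower were Ppargc1a (-2.99) of the oxidative and Casq1 (-1.34) of the contractile genes. Of 892 genes 542 were higher and 350 lower (496 and 420 with quantile normalization, 486 and 435 with centring).

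At Day 2 the metallothionein genes Mt2 (5.22 ± 0.78) and Mt1 (4.68), S100a8 (4.92), Chil3 (4.63), Lcn2 (4.59) and Ccl12 (4.41) were higher with GLA-SE than with GLA, and Aqp4 (-4.65 ± 0.44), the fast heavy chain gene Myh2 (-4.13 ± 0.62) and the sarcomere gene Myoz2 (-3.58) were lower. Oxidative genes were lower in 15 of 18 (median -1.13; Idh2 -2.08, Cox7a1 -1.85, Fabp3 -1.64; adjusted p = 0.0947 with an estimated correlation) and contractile genes in 6 of 24. Actb ends differed by 1.43 with GLA-SE and 0.89 with GLA, and Gapdh ends by 0.62 and 0.29, both without overlap. Interferon-stimulated genes were higher in 20 of 20 (median 2.84; Ifit1 3.75, Usp18 3.47), interferon-gamma-inducible genes in 13 of 13 (median 3.05), chemokines in 16 of 20 (median 2.61) and neutrophil markers in 5 of 6 (median 3.98), with adjusted p = 0.292, 0.338, 0.254 and 0.246 with an estimated correlation. Macrophage markers were higher in 8 of 12 (10 alone). All 14 lists called had adjusted p = 0.0947 to 0.453 with an estimated correlation. Of 948 genes 637 were higher and 311 lower, a split that centring moved to 529 and 432 and quantile normalization to 561 and 417.

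At Day 4 the macrophage genes Cd68 (4.86 ± 0.60), Clec4d (4.74), Lgals3 (4.73), Ms4a7 (4.70) and Ctss (4.64), with Saa3 (4.56), were higher with GLA-SE than with GLA, and the atrophy gene Fbxo32 (-1.58) was lower. Macrophage markers were higher in 12 of 12 (median 3.19), complement in 9 of 10 (median 2.43; C3ar1 4.39, C1qb 3.09) and MHC class II in 5 of 5 (H2-Aa 1.97), with adjusted p = 0.2, 0.31 and 0.383 with an estimated correlation. Interferon-stimulated genes were higher in 19 of 20 (median 1.98; Trim30a 2.99), interferon-gamma-inducible genes in 4 of 13 and chemokines in 9 of 20 (Ccl6 4.16), with adjusted p = 0.292, 0.679 and 0.445 with an estimated correlation. Extracellular matrix genes were higher in 8 of 18 (10 alone; Fn1 2.35). All 13 lists called at Day 1 and all 15 at Day 4 had adjusted p = 0.194 to 0.436 and 0.2 to 0.679 with an estimated correlation. Of 568 genes 549 were higher and 19 lower, 293 were called without replicate 1, 5 with only the groups compared in the fit, where Cd68, Lgals3, Ms4a7, Ctss, Saa3 and Fbxo32 lost their calls, and 954 with no filter. At Days 1, 2 and 4 the highest other division gave 43, 2 and 368 genes, and averaging probe sets gave 550, 611 and 344.

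**Figure D3:**
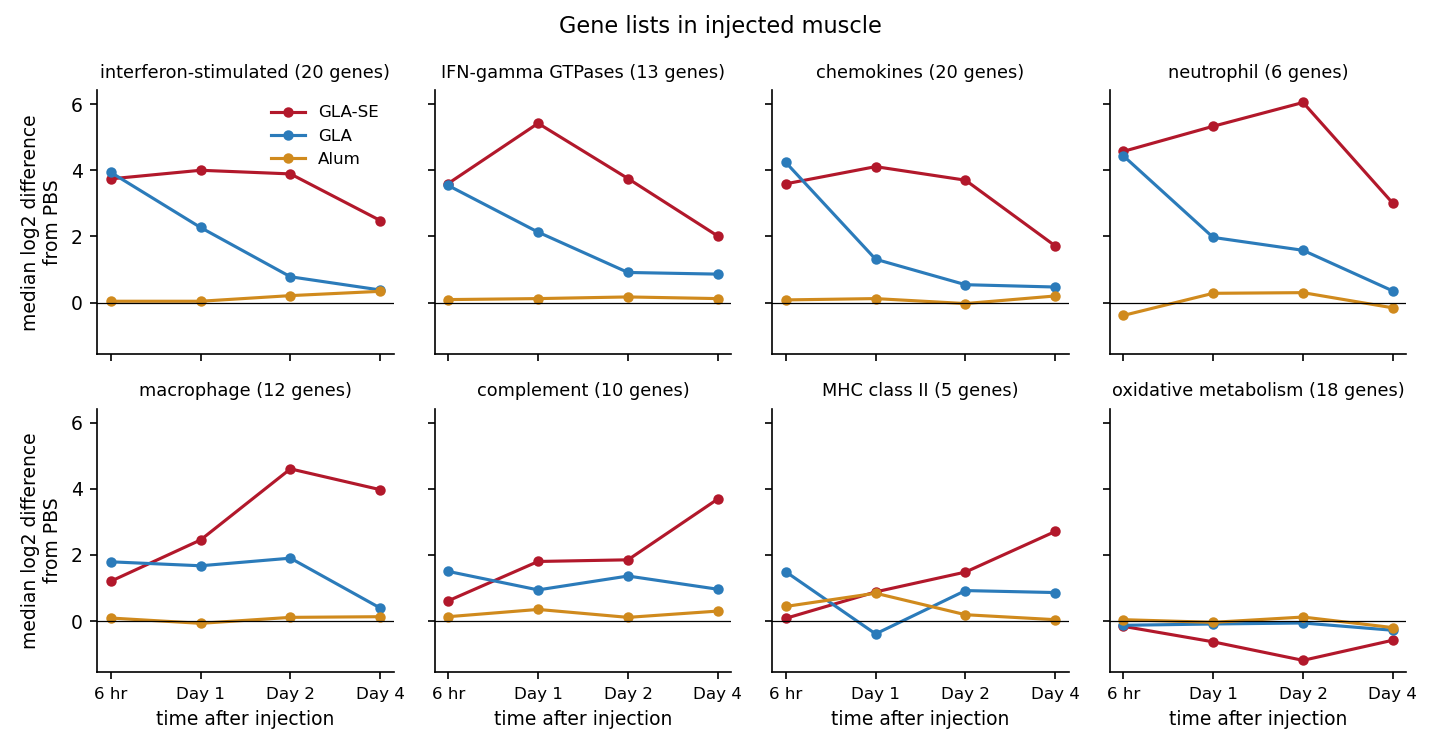
Lines give the median log2 difference from PBS over the tested genes of 8 lists in muscle at 6 hr and Days 1, 2 and 4 for GLA-SE, GLA and Alum, n = 3 per group. Interferon-stimulated genes stood at 3.74 with GLA-SE and 3.94 with GLA at 6 hr, then at 3.89 against 0.78 on Day 2, and oxidative genes with GLA-SE reached -1.19.

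Against Alum, Saa3 was higher with GLA-SE by 8.46 at 6 hr, 9.46 at Day 2 and 6.96 at Day 4, Slfn4 by 7.65 at 6 hr, Ankrd1 by 9.30 and Rrad by 8.55 at Day 1 and Ms4a7 by 5.63 at Day 4. Lower were Inmt (-2.67) at 6 hr, Ky (-5.75) at Day 1 and Aqp4 (-5.42) at Day 2. At 6 hr 456 genes were higher and 80 lower, at Day 1 666 and 596, at Day 2 778 and 545 and at Day 4 537 and 55. The medians of all genes were -0.12 at 6 hr and -0.13 at Day 1, relative to which Saa3 differed by 8.59, Inmt fell by 2.55, Ankrd1 differed by 9.43 and Ky fell by 5.62. Interferon-stimulated genes were higher in 20, 20, 20 and 19 of 20, interferon-gamma-inducible genes in 13, 13, 13 and 11 of 13 and chemokines in 12 (14 alone), 16 (17 alone), 18 and 11 of 20. Macrophage markers were higher in 5, 10, 11 and 12 of 12 (Mrc1 lower at Day 1, -1.92) and oxidative genes were lower in 1, 3, 16 and 1 of 18. Actb ends differed by 1.30 and 1.43 with GLA-SE at 6 hr and Day 2 against 0.57 and 0.64 with Alum, and Gapdh ends by 0.35 and 0.62 against 0.16 and 0.12, without overlap. Of the 13 lists called at 6 hr 4 were kept, and the rest had adjusted p = 0.0708 to 0.637 with an estimated correlation, with 0.182 to 0.606, 0.161 to 0.47 and 0.149 to 0.469 for the 15 lists lost at each later time. Counts were 353, 767, 843 and 364 with probe sets averaged, 829 at 6 hr and 940 at Day 4 with no filter, 383 at Day 4 without replicate 1 and 13 with only the groups compared in the fit, Ms4a7 not among them. Other divisions of the samples gave at most 0, 129, 0 and 511 genes.

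SE without GLA was measured in the smaller study against saline of Day 1. At 6 hr 3 genes rose, Gadd45g, a growth arrest gene (2.70 ± 0.29, adjusted p = 0.00373, n = 3), the clock gene Dbp (2.40 ± 0.38, adjusted p = 0.0338) and Zfp503 (2.13), and the clock gene Arntl fell (-2.12 ± 0.32, adjusted p = 0.0272). The control was taken at another time after injection, and saline muscle of the larger study differed between 6 hr and Day 1 by 2.53 in Dbp and -2.03 in Arntl. Without replicate 1 Gadd45g (2.88), Dbp (2.45) and Arntl (-2.15) were not called, without replicate 2 Dbp (1.90), Zfp503 (1.85) and Arntl (-2.02), and without replicate 3 Gadd45g (2.98), Dbp (2.85), Zfp503 (2.29) and Arntl (-2.18). The count was 2, 1 and 0 without replicates 1, 2 and 3, 1 with a replicate block, 7 with no filter, 18 in the joint fit of the studies, 21 without 2 Day 4 libraries and 24 with only the groups compared, and quantile normalization left 3 rises and 0 falls. No gene was called at Day 1 or Day 2, where limma gave unadjusted p below 0.05 for 36 and 7 of 4327 genes. Uneven SE Day 4 libraries widened the spread of this fit, so an effect of SE stays open. Day 1 medians were 2.46 for chemokines, 1.68 for macrophage markers, 1.21 for complement, 1.09 for acute phase and 0.94 for extracellular matrix genes. No member of these was called. Acute phase genes at 6 hr had a median of 0.42 (0 called, 2 alone) and endothelial markers at Day 2 -0.31. These lists had adjusted p = 0.464 to 0.477 with an estimated correlation. The 1, 8 and 3 lists called at 6 hr, Day 1 and Day 2 had adjusted p up to 0.926 with an estimated correlation.

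At Day 4 after SE the fat synthesis gene Elovl6 (5.13 ± 1.30), the retinol carrier gene Rbp4 (4.47), the citrate carrier gene Slc25a1 (4.47), Dgat2 (4.31) and Fasn (4.24) rose, each with adjusted p = 0.0222. The sarcomere genes Myom2 (-7.08 ± 2.04), Mybpc2 (-6.63), Myoz1 (-6.40) and Acta1 (-4.94) and the calcium release channel gene Ryr1 (-6.36) fell. Contractile genes fell in 22 of 24 (median -5.70, -5.43 relative to all genes), and adipocyte markers rose in 5 of 6 (median 3.00; Retn 4.38, Adipoq 3.78, Lipe 3.70), with adjusted p = 0.785 and 0.703 with an estimated correlation. MHC class I rose in 4 of 5, and oxidative genes fell in 5 of 18. The 11 lists called with the preset correlation had adjusted p = 0.703 to 0.926 with an estimated correlation. The changes lay in 2 of the 3 libraries, whose mean over 24 contractile genes was 2.51 and 2.57 beside 11.15 in replicate 1. In total 446 genes rose and 949 fell (570 and 756 with centring), and the median of all genes was -0.27, relative to which Elovl6 rose by 5.40, Rbp4 by 4.75 and Myom2 fell by 6.81. The count of 1395 stood beside 1369 for the highest other division, 2105 without replicate 1 and 0 without replicate 2 or 3, 0 with only the groups compared, 799 with probe sets averaged, 2100 in the joint fit and 0 without those 2 libraries. Actb probes at the 3' end exceeded those at the 5' end by 2.73 (SD 1.28) here and by 0.71 in saline. At 6 hr, Day 1 and Day 2 each other division gave 0 genes.

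**Figure D4:**
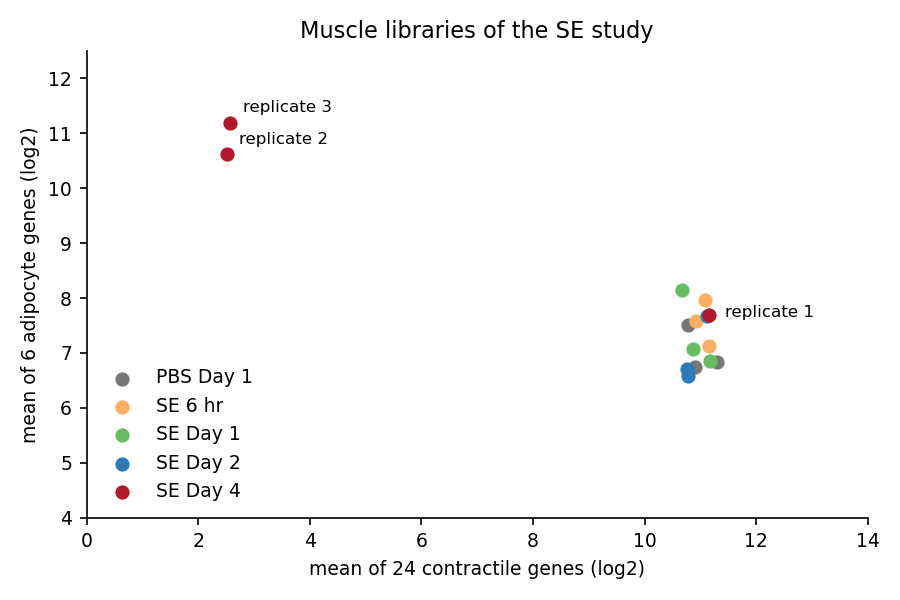
Each point is a muscle library of the smaller study, with the mean log2 signal of 24 contractile genes on one axis and of 6 adipocyte genes on the other, for SE at 6 hr and Days 1, 2 and 4 and PBS at Day 1 (3 libraries each). Replicates 2 and 3 of SE Day 4 stand apart at 2.51 and 2.57 for contractile and 10.62 and 11.19 for adipocyte genes.

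Across the studies, the Day 1 effect of GLA-SE exceeded that of SE most in Cxcl9 (7.87 ± 1.03, adjusted p = 1.58e-07, n = 3), Cd274 (6.61 ± 0.76), Saa3 (6.34), Il6 (6.17 ± 0.46, adjusted p = 1.17e-13) and Ubd, a ubiquitin-like gene of the interferon response (5.84). Ankrd1 (7.32) was no longer called without replicate 2 (4.68), and Ky (-5.39 ± 1.12) was not called without replicate 3 (-4.80). Of 5966 genes 426 were higher and 307 lower. Interferon-stimulated genes were higher in 19 of 20 (median 2.99; Irf7 3.55, and Ifit1 3.81, a call lost without replicate 2 at 3.01 or 3 at 3.69) and interferon-gamma-inducible genes in 13 of 13 (median 4.95), with adjusted p = 0.322 and 0.252 with an estimated correlation. Chemokines were higher in 13 of 20 with Pf4 lower (-2.71) and TLR4 pathway genes in 12 of 15. The 12 lists called with the preset correlation had adjusted p = 0.252 to 0.964 with an estimated correlation. The count of 733 became 1134 without replicate 1, 310 without replicate 3 and 450 with probe sets averaged. Of 100 ways to divide the samples 13 gave at least as many, the real one included. The 12 others kept GLA-SE apart from its control and so held its effect (highest 1588). Divisions that mixed the 2 (at most 55) removed it, so chance was left open.

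The Day 1 effect of GLA-SE exceeded the sum of the GLA and SE effects most in Ankrd1 (8.86 ± 1.81), Hspa1a (7.72 ± 1.17), Hspa1b (6.97), Rrad (6.84), Il6 (5.66 ± 0.46, adjusted p = 2.34e-12), Ubd (4.84), Thbd (4.70) and Cd274 (4.53). Rrad was not called without replicate 3 (5.80), and Ky (-5.19) and Mylk4 (-4.47) lost their calls without replicate 2 (-5.24 and -5.08) or 3 (-4.56 and -3.99). Saa3 (-1.37, adjusted p = 0.47 by limma) and Ifit1 (0.40) were not called against the sum. Interferon-gamma-inducible genes exceeded it in 7 of 13 (11 alone; median 2.42; Gbp6 3.53), while interferon-stimulated genes did in 1 of 20 (median 0.60), with adjusted p = 0.322 and 0.981 with an estimated correlation. Cytokines were higher in 4 of 7 (Il1rn 2.41, and Il1b 3.16, a call lost without replicate 3 at 2.32), regeneration genes in 3 of 5 (Gadd45a 2.87, Myf6 2.82) and chemokines in 7 of 20 (8 higher and 3 lower alone). The 9 lists called with the preset correlation had adjusted p = 0.252 to 0.981 with an estimated correlation. Of 394 genes 276 were higher and 118 lower (274 and 162 with quantile normalization, 234 and 170 with centring), 698 were called without replicate 1, 208 without replicate 2, 125 without replicate 3 and 225 with probe sets averaged. Of 100 divisions 6 gave at least as many. The 5 others kept GLA-SE apart from GLA and so still held that difference (highest 1000, against 73 for divisions that mixed the 2), so they did not decide on chance either.

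The saline muscle of Day 1 differed between the studies, with 2 genes higher and 214 lower in the smaller one. The nuclear RNA Malat1 was higher by 3.35 ± 0.42 and Itsn1 by 1.01, and the haem synthesis gene Cpox (-2.58 ± 0.22, adjusted p = 2.08e-12, n = 3), Nufip2 (-2.28), Ptpn6 (-2.28) and Ccl2 (-2.32; not called without replicate 3, -1.53, or with quantile normalization, -1.72) were lower. Relative to the median of all genes (-0.36) Malat1 was higher by 3.71 and Cpox lower by 2.23. Quantile normalization gave 9 higher and 22 lower and centring 11 and 47, and no filter gave 1450. Contractile genes had a median of -0.23 and a mean of -0.50, and extracellular matrix genes -0.25 and -0.21, yet camera ranked both upward relative to all genes, with adjusted p = 0.981 and 0.964 with an estimated correlation. Chemokines were lower in 5 of 20, and each other division of the samples gave 0 genes.

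Saline muscle of the larger study varied between times in 55 genes. Ranges were largest for the metallothionein genes Mt2 (4.46, adjusted p = 0.000557, n = 3 at each time) and Mt1 (3.53), Pdk4, which holds back glucose oxidation (3.83, adjusted p = 2.24e-07), the receptor gene Nr4a3 (3.22), Dbp (2.53) and Ucp3 (2.49). Mt2 (4.08) and Mt1 (3.01) were not called without replicate 2, nor Dbp (2.51) without replicate 1. The count was 18, 44 and 32 without replicates 1, 2 and 3, 31 with probe sets averaged and 88 with no filter. The real division gave more genes than each of 99 others (highest 42).

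In the lymph node at 6 hr after GLA-SE, Saa3 rose from 2.05 to 10.49, by 8.45 ± 0.58 or 349-fold against saline of Day 1 (n = 3 each, adjusted p = 1.54e-06). The chemokine genes Cxcl11 (7.19), Cxcl10 (6.75), Ccl3 (6.66) and Cxcl2 (6.55), Slfn4 (6.97), Il6 (6.96 ± 0.50, 125-fold) and the itaconate synthesis gene Acod1 (6.67) rose with it. Inmt fell (-2.73 ± 0.30). Of 5747 genes 287 rose and 62 fell, and relative to the median of all genes (-0.11) Saa3 rose by 8.56 and Inmt fell by 2.61. All 24 interferon-stimulated genes (median 3.69, 3.81 relative to all genes), 13 of 14 interferon-gamma-inducible genes (median 2.59), 13 of 20 chemokines (median 4.11; Cxcl12 fell, -1.17) and 6 of 6 neutrophil markers (median 4.15) rose, with adjusted p = 0.0869, 0.0869, 0.0869 and 0.0873 with an estimated correlation. Cytokines rose in 5 of 7, TLR4 pathway genes in 8 of 16, acute phase genes in 8 of 12 (9 alone), macrophage markers in 3 of 13 (Fcgr1 3.77; Csf1r fell, -1.09), and dendritic cell (Cd40 1.32) and NK cell genes (Gzmb 4.32) in 1 each. Ifng rose by 5.26, a call lost without replicate 2 (3.83) or 3 (5.12) and with only the groups compared in the fit. No T cell, cell cycle, MHC class II, oxidative or adipocyte gene was called. The 13 lists called with the preset correlation had adjusted p = 0.0869 to 0.648 with an estimated correlation, and 185 genes were left without replicate 3 and 590 called with no filter.

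At Day 1 in the node 348 genes rose and 234 fell. Saa3 (8.46, 353-fold), Cxcl11 (8.06 ± 0.58, 267-fold), Slfn4 (7.29), Acod1 (6.98), Lcn2 (6.90) and Ifit1 (6.68 ± 0.36) led the rises, and Ifng was up by 5.30, a call lost without replicate 2 (4.52) or 3 (4.46). Among the largest falls were Il22ra2 (-4.89 ± 0.37), the transporter gene Abca8a (-4.57), Inmt (-4.48 ± 0.30), the mannose receptor gene Mrc1 (-4.00) and the marginal and sinus macrophage gene Cd209b (-5.59 ± 1.22; not called without replicate 2, -5.24). All 24 interferon-stimulated genes (median 4.32), 13 of 14 interferon-gamma-inducible genes (median 2.90), 11 of 20 chemokines (median 3.22; Cxcl12 fell, -2.29) and 5 of 6 neutrophil markers (6 alone; median 4.07) rose, with adjusted p = 0.0873, 0.0873, 0.158 and 0.158 with an estimated correlation. MHC class I rose in 7 of 10 and NK cell genes in 2 of 7 (Gzmb 4.84, Gzma 2.87). Of the macrophage markers 5 of 13 rose (Fcgr1 4.70) and 2 fell (3 alone; Mrc1, Csf1r -1.95), and extracellular matrix genes rose in 2 of 18 (Timp1 5.10, Mmp3 1.76) and fell in 4 (Lum -3.55, Postn -2.80). Fcer2a, the low-affinity IgE receptor of B cells (-3.13), and Jchain, the joining chain of secreted antibody (-2.67), fell, and no T cell gene was called. The 14 lists called had adjusted p = 0.0873 to 0.707 with an estimated correlation, and the count was 379 without replicate 2, 357 with probe sets averaged and 1148 with no filter (459 rises and 689 falls).

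At Day 2 the node had Saa3 (8.14), Acod1 (6.76), Fpr2 (6.23), Slfn4 (6.22) and the lectin genes Clec4d (5.52) and Clec4e (5.30) raised, and Inmt (-3.97), Il22ra2 (-3.19) and Cd209b (-5.91; not called without replicate 2, -5.85) lowered, in all 216 rises and 79 falls. Cell cycle genes rose in 4 of 14 (8 alone; median 1.05; Rrm2 1.96, Cdk1 1.69; adjusted p = 0.204 with an estimated correlation). All 24 interferon-stimulated genes (median 2.81), 12 of 14 interferon-gamma-inducible genes (median 1.91), 11 of 20 chemokines (13 alone; Cxcl12 fell, -1.16) and 4 of 6 neutrophil markers (5 alone; median 4.02) rose, with adjusted p = 0.0873, 0.0873, 0.135 and 0.138 with an estimated correlation. Of the macrophage markers 6 of 13 rose (Chil3 3.60) with Mrc1 lower (-1.94), and NK cell genes rose in 2 of 7 (3 alone; Gzmb 4.22, Gzma 3.20). The plasma cell gene Mzb1 rose (1.01) and Fcer2a fell (-1.37). The 14 lists called had adjusted p = 0.0873 to 0.594 with an estimated correlation, and 117 genes were left without replicate 2 and 554 called with no filter.

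At Day 4 antibody and division genes were raised in the node. Ighg3, the constant region of IgG3 (probe set 1427503_at, chromosome 12 at 113357442 to 113361232), rose from 3.90 (SD 2.61) to 9.86 (SD 0.18), by 5.97 ± 0.99 (adjusted p = 0.00087, n = 3), beside Saa3 (6.90), Fpr2 (5.95), Clec4e (5.62), Ptgs2 (5.29) and Acod1 (5.29). Plasma cell genes rose in 3 of 4 (Mzb1 2.63, Jchain 1.43, Xbp1 1.15; median 1.29) and cell cycle genes in 8 of 14 (Rrm2 2.33, Mki67 2.20, Top2a 2.06, Cdk1 2.02; median 1.52, 1.73 relative to all genes), with adjusted p = 0.0873 and 0.182 with an estimated correlation, and the B cell gene Ms4a1 rose by 1.57. The same libraries had Actb probes at the 3' end only 1.76 (SD 0.20) above the 5' end, against 4.07 to 4.40 in the other node groups. Inmt (-4.59), Abca8a (-4.15), Timd4 (-3.43), Cd209b (-5.66; not called without replicate 2, -5.25) and the muscle genes Myh1 (-3.98) and Myh4 (-3.53) fell, and contractile genes fell in 12 of 13 (13 alone; median -2.91, -2.70 relative to all genes; adjusted p = 0.385 with an estimated correlation). Adipocyte markers had a median of -2.81 (-2.60 relative to all genes) with 0 of 9 called. Relative to the median of all genes (-0.21) Saa3 rose by 7.12, Ighg3 by 6.18, Inmt fell by 4.38 and Myh1 fell by 3.77. Of the 559 genes called 290 rose and 269 fell, and 392 and 143 with quantile normalization or 388 and 155 with centring, but 298 and 393 with a replicate block and 485 and 964 with no filter.

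Interferon-stimulated genes rose in 12 of 24 in the Day 4 node (median 1.17, 1.38 relative to all genes), interferon-gamma-inducible genes in 11 of 14 (12 alone; median 1.94), chemokines in 6 of 20 (median 1.25; Ccl22 fell, -1.82) and neutrophil markers in 3 of 6 (median 2.59), with adjusted p = 0.19, 0.0873, 0.182 and 0.204 with an estimated correlation. Of the macrophage markers 6 of 13 rose (7 alone; Ccr2 2.60) while Marco (-2.96) and Mrc1 (-2.30) fell, and NK cell genes rose in 2 of 7 (Gzmb 2.95, Gzma 2.97). No T cell, MHC class II or oxidative gene was called in the node at any time, and Cd3e, a part of the T cell receptor complex, differed from saline by 0.20, 0.12, -0.24 and 0.07. The 15 lists called had adjusted p = 0.0873 to 0.455 with an estimated correlation, and no filter gave 1449 genes. From 6 hr to Day 4 other divisions gave at most 21, 0, 11 and 173 genes, against 349, 582, 295 and 559.

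**Figure D5:**
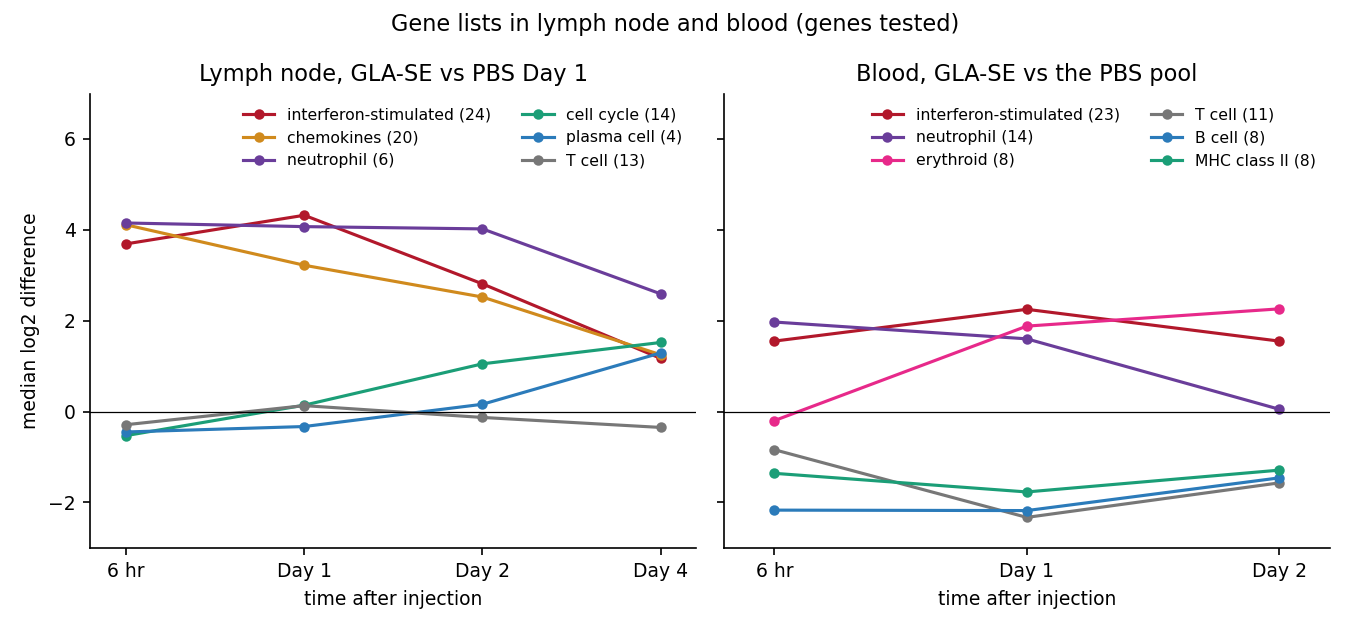
Lines give the median log2 difference from saline over the tested genes of each list after GLA-SE, in lymph node (6 hr to Day 4, saline of Day 1, n = 3) and in blood (6 hr to Day 2, 1 pooled saline sample). In the node interferon-stimulated genes went from 4.32 on Day 1 to 1.17 on Day 4 and cell cycle genes reached 1.52, and in blood T cell markers stood at -2.33 and erythroid markers at 1.88 on Day 1.

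In blood at 6 hr after GLA-SE, neutrophil genes rose over the pooled saline sample. Prok2, a secreted attractant made by neutrophils (probe set 1419681_a_at, chromosome 6 at 99711299 to 99726392), rose from 1.06 to 7.44 (SD 0.30, n = 3 against 1), by 6.38 ± 0.43 or 83.2-fold (adjusted p = 6.92e-05). The lipase gene Lipg (5.73), the decoy receptor gene Il1r2 (4.82), Acod1 (4.47), Ngp (4.19), Mmp8 (4.07) and Cd14 (3.45) rose, and the B cell genes Fcer2a (-2.96) and Vpreb3 (-2.81) and the replication gene Pclaf (-2.39) fell. Neutrophil markers rose in 10 of 14 (12 alone; median 1.97, 2.08 relative to all genes; adjusted p = 0.529 with an estimated correlation) and interferon-stimulated genes in 5 of 23 (14 alone; median 1.55; adjusted p = 0.638 with an estimated correlation). B cell genes fell in 1 of 8 (6 alone; median -2.17; adjusted p = 0.638 with an estimated correlation), MHC class II in 1 of 8 (5 alone), T cell genes in 0 of 11 (2 alone) and cell cycle genes in 3 of 7 (4 alone). TLR4 pathway genes rose in 3 of 15 (5 alone) and monocyte markers in 0 of 11 (1 alone). Of 4054 genes 136 rose and 33 fell, and relative to the median of all genes (-0.11) Prok2 rose by 6.49, Lipg by 5.84 and Fcer2a fell by 2.85. The pool was assumed to vary like the treated samples, so the p-values and calls against it at all 3 times do not measure how saline blood varies. The count was 283, 67 and 72 without replicates 1, 2 and 3, and quantile normalization gave 288.

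At Day 1 antiviral genes rose in blood, with Oasl2 (5.60 ± 0.59, 48.4-fold, adjusted p = 0.00021), Oas3 (4.97) and Usp18 (4.55), beside Lipg (5.43), the neutrophil granule gene Ltf (4.71) and the amino acid stress genes Atf5 (4.80) and Asns (4.51). T cell genes fell, led by Cd8b1 (-4.61 ± 0.63, 24.4-fold) and Cd5 (-3.27). The median of all genes was -0.46, relative to which Oasl2 rose by 6.05 and Cd8b1 fell by 4.15 and Cd5 by 2.81. Of the T cell genes 10 of 11 fell (median -2.33, -1.87 relative to all genes; Cd247 -2.74, Cd3g -2.71) and Zap70 rose (1.19), B cell genes fell in 7 of 8 (median -2.18, -1.72 relative to all genes; Fcrla -2.41) and MHC class II in 6 of 8 (7 alone; -1.31 relative to all genes). Interferon-stimulated genes rose in 21 of 23 (median 2.25, 2.71 relative to all genes), interferon-gamma-inducible genes in 10 of 12, erythroid markers in 6 of 8 (median 1.88, 2.34 relative to all genes; Epb42 2.99, Rhd 2.73, Trim10 2.50) and neutrophil markers in 7 of 14 (median 1.60, 2.06 relative to all genes). Adjusted p = 0.638, 0.529 and 0.658 with an estimated correlation for the interferon-stimulated, erythroid and T cell lists. Oxidative genes fell in 6 of 14 (median -0.77, -0.31 relative to all genes) and NK cell genes in 2 of 4 (median -0.79, -0.33 relative to all genes), cell cycle genes rose in 2 of 7 (Nusap1 1.23, Ccna2 1.18) and fell in 3, and platelet genes rose in 1 of 8. In all 453 genes rose and 1147 fell, a split of 709 and 571 with quantile normalization and of 796 and 521 with centring.

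At Day 2 Oasl2 (5.97), Atf5 (5.76), Oas3 (4.72) and the folate enzyme gene Mthfd2 (3.87) were raised in blood and Cd8b1 (-3.17), Acta2 (-2.68) and Thy1 (-2.40) lowered. Relative to the median of all genes (-0.52) Oasl2 rose by 6.49, Atf5 by 6.28 and Cd8b1 fell by 2.65. Interferon-stimulated genes rose in 14 of 23 (15 alone; median 1.55, 2.07 relative to all genes) and erythroid markers in 6 of 8 (median 2.26, 2.78 relative to all genes), and T cell genes fell in 9 of 11 (median -1.57, -1.05 relative to all genes) with Zap70 up (1.03). Adjusted p was 0.638, 0.529 and 0.762 with an estimated correlation. Neutrophil markers rose in 3 of 14 (median 0.05, 0.57 relative to all genes) and B cell genes fell in 1 of 8. In all 399 genes rose and 885 fell (585 and 296 with quantile normalization, 635 and 162 with centring), and the larger number of falls turned with the scaling.

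From 6 hr to Day 2 in blood, with 3 samples on each side, Atf5 (4.78), the cohesin gene Esco2 (4.18), the red cell membrane gene Epb42 (3.83) and Pck2 (3.71) rose and Lipg (-5.60), Il1r2 (-4.91), Prok2 (-4.83) and Cd14 (-3.07) fell. Relative to the median of all genes (-0.48) Atf5 rose by 5.26, Epb42 by 4.30 and Lipg fell by 5.13. Neutrophil markers fell in 10 of 14 (median -1.65, -1.17 relative to all genes; Mmp8 -4.00), TLR4 pathway genes in 10 of 15 (median -1.28, -0.80 relative to all genes; Bcl3 -2.46) and acute phase genes in 4 of 5, and erythroid markers rose in 6 of 8 (median 2.29) and cell cycle genes in 4 of 7 (Ccna2 2.29, Mki67 1.77). The neutrophil list had adjusted p = 0.776 with an estimated correlation. Of the interferon-stimulated genes 7 of 23 rose while Trim30a fell (-1.72), and monocyte markers fell in 4 of 11 (median -0.96, -0.48 relative to all genes). The lists called in blood numbered 14, 6, 5 and 6, all lost, with adjusted p = 0.529 to 0.776 and, for Day 2 against 6 hr, 0.529 to 0.841 with an estimated correlation. In all 395 genes rose and 669 fell (524 and 325 with quantile normalization, 569 and 269 with centring), and averaging probe sets gave 844, 634 and 627 genes for Day 1, Day 2 and Day 2 against 6 hr. With no filter Day 1 gave 3284 and Day 2 against 6 hr 1689, and centring gave 797 at Day 2. Each other division of the 6 hr and Day 2 samples gave 0 genes. With 1 pooled saline sample the other blood contrasts could not be divided.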

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

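The tests of adipose tissue, degraded RNA, a change in every animal given SE, a partner for an exchange, lymph node tissue in the samples and intact node RNA, the differences between times and the look at the Actb probes were chosen after the result was seen, the tests of an exchange of libraries, of muscle carried over and of the hour of the day after the pattern was seen but before their own values were, and the divisions of the samples and the 2 contrasts across the studies before the data were examined.

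The difference between GLA-SE and GLA in muscle was itself tested between times: against 6 hr it differed in 965 genes at Day 1 (534 higher, 431 lower), 1114 at Day 2 (725 and 389) and 818 at Day 4 (698 and 120), with interferon-stimulated genes higher in 11, 20 and 17 of 20, macrophage markers in 4, 12 and 12 of 12 and chemokines in 13, 15 and 7 of 20. The Day 1 effect of GLA-SE on muscle differed from that of SE in 733 genes. It differed from the sum of the GLA and SE effects in 394. Of 100 divisions of the samples 13 and 6 gave as many (highest others 1588 and 1000). The 12 and 5 others kept GLA-SE apart from its control and so held its effect. Divisions that mixed the 2 (at most 55 and 73 genes) removed it, so chance was left open. In SE Day 4 muscle the Actb control probes, which no comparison used, stood 2.73 (SD 1.28) higher at the 3' than at the 5' end, against 0.71 in saline.

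At Day 4 after SE, replicates 2 and 3 nearly lacked muscle transcripts (contractile means 2.51 and 2.57, against 10.67 to 11.29 in the 13 other libraries of that study) and held adipocyte transcripts (10.62 and 11.19), at least 2.48 above any other library of that study (over 10 adipocyte genes a node library reached 8.82, against 8.56 in replicate 2 and 9.34 in replicate 3), with Adipoq at 11.19 and 11.78 and Ckm at 3.86 and 3.99. Degraded RNA alone was argued against by the rise of adipocyte genes (median 3.00), and a change in every animal by replicate 1 at 11.15 for contractile genes. The highest correlation with a lymph node or blood library, 0.962, met what had been written for an exchange of libraries, but an exchange needs a muscle library among the node and blood samples, and the highest contractile mean there was 6.08. Lymph node tissue in the sample was borne out for replicate 2 (T cell mean 4.72, against 5.29 to 6.65 in nodes and at most 0.80 in other muscle) and argued against for replicate 3 (0.60). A candidate explanation is adipose tissue under a muscle label, with lymph node in replicate 2, and which tissue was taken stays open.

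At Day 4 the lymph node had 269 lowered genes, muscle genes such as Myh1 among them. Less muscle carried over with the node was argued against as the whole cause, since 12.3% of these genes (33) were at least 4-fold higher in saline muscle than in the saline node, against 3.2% of all tested genes. Adipocyte markers had a median of -2.81 there with 0 of 9 called, and less fat carried over was not tested. RNA more intact than in the other node samples cannot be told apart from the time: the Actb 3' to 5' difference of Day 4 lay 1.77 below the lowest other node sample, and no other group shared that time. Cell cycle genes were already higher at Day 2 (median 1.05) without more intact RNA, which argued against that cause there. At Day 4 it stays open. A biological fall of the 269 genes at Day 4 was not tested apart from RNA quality.

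At 6 hr after SE the clock genes Dbp (2.40) and Arntl (-2.12) differed from Day 1 saline. The same difference was seen in saline of the other study between 6 hr and Day 1 (2.53 and -2.03), and of 17 clock genes listed 6 were tested in both studies. The 4 besides Dbp and Arntl, none of them called after SE (-0.87 to 0.50), had the same sign in both, with r = 0.99 across genes that are few and not independent. The hour of the day is a candidate source, and at Day 1 after SE Dbp (-0.09) and Arntl (0.06) were not called. An effect of SE on these genes at 6 hr stays open, since no 6 hr saline was taken in that study.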

How the results depend on the processing

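Centring and the fit without 2 SE Day 4 libraries were chosen after the result was seen, the other alternatives before the data were examined. Across 15 kinds of alternative and 362 counts of called genes, 254 stayed within 1.5 times the value reported and 107 moved further, apart from the list count. Of the values of named genes 7521 kept direction and side of the threshold, 530 lost the call, 63 gained one and 1 reversed. Saline close to background (most values below log2 5) limits folds of induced genes, groups of 3 limit precision, and the cause was not tested except where the alternative's construction shows it.

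The mean of all probe sets of a gene, with which fewer genes passed the filter (3380 against 5857 in muscle of the larger study), gave for GLA-SE against PBS 319, 809, 834 and 395 genes (6 hr, Days 1, 2 and 4), for GLA 370 at 6 hr, 37 at Day 2 and 6 at Day 4, for Alum 0 at 6 hr, for GLA-SE against GLA 550, 611 and 344 at Days 1, 2 and 4, against Alum 353, 767, 843 and 364, for SE Day 4 799, for the node at Day 1 357, for blood 844, 634 and 627 (Day 1, Day 2, Day 2 against 6 hr), for GLA-SE minus SE 450, minus the sum 225 and for saline between times 31. No filter, which tests more genes, gave 982 for GLA-SE at Day 4, 37 and 22 for GLA at Days 2 and 4, 6 and 6 for Alum at 6 hr and Day 4, 954 against GLA at Day 4, 829 and 940 against Alum at 6 hr and Day 4, 7 for SE at 6 hr, 590, 1148, 554 and 1449 in the node, 3284 and 1689 in blood (Day 1, Day 2 against 6 hr), 1450 between the studies and 88 for saline between times. Only the groups compared in the fit gave 312 for GLA-SE at Day 4, 17, 8 and 0 for GLA at Days 1, 2 and 4, 0 for Alum at 6 hr, 42 and 5 against GLA at 6 hr and Day 4, 13 against Alum at Day 4, and 24 and 0 for SE at 6 hr and Day 4.

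Saline of all times pooled gave 223, 130 and 4 for GLA at Days 1, 2 and 4 and 26 for Alum at 6 hr. The random block gave 128 and 32 for GLA at Days 2 and 4, 6, 2 and 2 for Alum at 6 hr, Day 1 and Day 4 and 162 for GLA-SE against GLA at 6 hr. Samples of the same replicate number did not all deviate together: mean r was 0.01 in muscle of the larger study, -0.11 in the smaller, 0.27 in the node (-0.14 for other numbers) and 0.06 in blood, with 34.7%, 30%, 66.7% and 33.3% of pairs over 0.1, and 20 of 48, 0 of 15, 9 of 15 and 5 of 9 samples were closest to their own number. The node values hint at a shared source there, though the lowest pair had -0.49. The replicate block gave 1 for SE at 6 hr and left 30 of 31 counts within 1.5 times, with 688 (357 higher, 331 lower) and 691 (298 and 393) in the node at Days 1 and 4. Both studies in a joint fit gave 18 for SE at 6 hr and 2100 at Day 4, and the fit without 2 SE Day 4 libraries gave 21 at 6 hr, 1 at Day 1 and 0 at Day 4, where Acta1 reversed from -4.94 to 0.059 because the libraries that carried its fall were left out. Quantile normalization gave 288 for blood at 6 hr and 31 between the studies, and centring 797 for blood at Day 2 and 58 between the studies. The estimated correlation left 14 of 371 list calls. Trend and robust moved 0 of 4 counts.

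With each replicate left out in turn, counts ran from 306 to 688 for GLA at 6 hr, 11 to 188 at Day 1, 1 to 108 at Day 2 and 0 to 3 at Day 4, were 0 each time for Alum at 6 hr and 0 to 1 at Day 4, ran from 52 to 82 for GLA-SE against GLA at 6 hr and 293 to 822 at Day 4, 383 to 741 against Alum at Day 4, 0 to 2 for SE at 6 hr and 0 to 2105 at Day 4, 185 to 366, 379 to 619 and 117 to 277 for the node at 6 hr, Day 1 and Day 2, 67 to 283 for blood at 6 hr, 310 to 1134 for GLA-SE minus SE, 125 to 698 minus the sum and 18 to 44 for saline between times. The other counts stayed within 1.5 times without any 1 replicate. The spread of the 1 blood saline sample was assumed equal to that of the others.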

Other observations

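No test of this part, the divisions of the samples, was chosen after the result was seen.

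In muscle given GLA-SE the counts of called genes in a list varied between times, a variation that was not tested. Inflammatory cytokines rose in 6, 7, 6 and 4 of 7 genes (6 hr, Days 1, 2 and 4), and Csf3 went from 4.58 to -0.16, while macrophage markers rose in 5, 10, 12 and 12 of 12, complement in 2, 7, 8 and 9 of 10 and MHC class II in 0, 1, 3 and 5 of 5. Oxidative genes fell in 1, 2, 15 and 1 of 18. With an estimated correlation only the cytokine list at 6 hr was called among these. Saa3 was raised in muscle and in lymph node at all times measured, by 7.28 to 9.47 and by 6.90 to 8.46.

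For contrasts of 3 samples with 3 only 10 divisions exist, too few for a share under 0.05. Only the real division, 1 of 10, gave as many genes in every such contrast with called genes. For Alum at Days 1, 2 and 4 and SE at Days 1 and 2 all 10 gave 0. The real count and the highest other lay close for GLA-SE against GLA at 6 hr (107 and 105), against Alum at Day 4 (592 and 511) and for SE at Day 4 (1395 and 1369), and were furthest apart for GLA-SE against Alum at Day 2 (1323 and 0) and against PBS at Day 2 (1297 and 0). For the 2 differences of effects 13 and 6 of 100 divisions gave as many genes, shares over the 0.05 written beforehand as the mark of chance. The others kept GLA-SE apart from its control and so did not decide on chance. Chance was argued against, but not excluded, for saline between times, where 1 of 100 divisions, the real one, gave 55 genes and the highest other 42.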
